A study of Mus musculus with 18 samples.

How the data were processed

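The deposited table gave small RNA read counts of mouse kidney for 18 libraries, with a raw and a normalized column for each library. Per the labels, the authors extracted RNA with Trizol, made libraries with a TruSeq Small RNA kit and sequenced them on an Illumina HiSeq. According to the labels, reads were filtered with ACGT101-miR, which removed adapter dimers, junk, low-complexity sequences, common RNA families and repeats. The submitters' processing notes also name Trimmomatic 0.32, BWA, SAMtools and edgeR, without versions for the last 3. What each program did, the genome build and the miRBase release are not given in the sources used here.

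The raw columns of the deposited table held estimated counts: 76.9% of the values above 0 were exactly whole and the others had decimals. The normalized columns of the deposited table held a signal, which was the raw value times 1 factor per library (0.6644 to 1.427), and how the authors found that factor is not given in the sources used here. The table had 1534 entries, of which 350 had no name. These unnamed entries held between 0.0136% and 0.148% of the counts of a library and were left out. Of the 1184 named entries, 814 had a mouse name (prefix mmu in the table, left out here) and 370 were named for another species, and 118 names stood on more than 1 entry. Raw values of 429 entries equalled those of another named entry exactly in every library. Estimated counts were rounded to whole numbers, which changed no library's total by more than 0.00044%.

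The 3 comparisons were fitted with edgeR 4.0.16 in R 4.3.3 on all 18 libraries together, with the group as the only factor. Entries passed filterByExpr by group (minimum count 10, minimum total 15), which kept 619 entries with 99.972% of the named counts and removed 565. The kept entries carried 505 names, 426 of them annotated mouse miRNA arms. Library sizes were scaled with TMM factors, and the quasi-likelihood test (legacy method, without the robust prior) was 2-sided, with Benjamini-Hochberg adjustment over the 619 entries and a threshold of adjusted p under 0.05. Log2 fold changes (log2FC) are those of the fit, with a standard error (SE) from the working weights and the posterior quasi-dispersion, and 95% intervals (CI) where printed. Levels are CPM, as the cpm function of edgeR gives them with the TMM factors, given as mean ± SD over the 6 libraries of a group, and log2 CPM used a prior count of 2. Separation means that every library of one group lay above every library of the other, which chance gives in 0.216% of entries.

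The 20 lists were drawn up from general knowledge. Families and pathways were injury- and fibrosis-associated miRNAs, the miR-29 and miR-200 families, kidney-enriched miRNAs, the miR-30 family, the let-7 and miR-98 family, miR-17-92 and its paralogous clusters, a list for hypoxia, oxidative stress and nutrient sensing, and a list for NF-kB and innate inflammation. Genomic clusters were the imprinted Dlk1-Dio3 cluster, the Sfmbt2 intron cluster, the X-linked miR-322 and miR-503 cluster, the miR-183, miR-96 and miR-182 cluster and miR-188 with its Clcn5 neighbours. Cell type markers covered endothelial cells, a joint list for smooth muscle, mesangial cells and pericytes, leukocytes, red blood cells, striated muscle, liver, and a joint list for nerve, adrenal and islet cells. Each of the 19 lists with at least 3 tested entries was compared with the other entries by camera (limma 3.58.1, preset correlation 0.01), adjusted over all 57 tests. Camera with an estimated correlation and fry, which asks whether the members of a list move on balance one way without comparing them with other entries, were run as alternatives. The level of a list in a library is the mean log2 CPM of its entries, each relative to its mean over all 18 libraries.

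Choices made before the data were examined were the groups, the tests, the 20 lists, the first set of alternatives and the rule for naming miRNAs. By that rule a mouse miRNA was named in a comparison if it was among up to 10 with the largest change past the threshold in each direction at a mean of at least 10 CPM, or was a list member past the threshold. Where fewer than 5 passed in a direction, those of smallest unadjusted p were named up to 5, with values only. The miRNAs miR-188-3p, miR-21a-5p, miR-192-5p, miR-29c-3p, miR-200a-3p and miR-451a were named in each comparison, and the 5 most abundant were named once. Other miRNAs named as list examples, in the overlap or among the results of a list taken alone were picked after their values were seen.

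Alternatives were RLE factors, library size only, no filter, a filter of 10 CPM in 6 libraries, DESeq2 1.42.0, limma-voom with sample weights, the replicate number as a block, only the 2 groups compared, entries of one name summed, an added fold threshold, and each library left out in turn. Added after seeing the data were leaving out control 2, DN 2 and DN 3 together, the robust prior, the edgeR 4 quasi-likelihood method, the authors' factors, equal entries kept once, list tests with each library left out in turn, and list tests with an estimated correlation on fewer libraries or under library size only. The overlap of opposite changes was compared with 100 simulations in which all 3 groups were drawn from the same means. In these, DN and control did not differ either. It was also compared with 20 splits of the DN libraries into sets of 3, fitted with the edgeR 4 quasi-likelihood method. Splits in which the 3 libraries with the lowest median r to their own group were left out anew were added last.

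Simulated counts tested the procedure with the dispersion fitted to each entry. Entries were drawn independently and without outlying libraries. Each run planted 100 entries at 2-fold and 100 at 4-fold among 619, and many planted changes ease the adjusted threshold. The shares called may thus be higher than in the real data. Of 100 entries planted at 2-fold, 50, 49 and 57 were called in DN against control, treated against DN and treated against control, and at 4-fold 81, 88 and 75 of 100 were called. Among 419 unchanged entries 5, 6 and 5 were called. In 20 simulations for each comparison, the miR-30 and Dlk1-Dio3 lists planted at 2-fold were called in 20 of 20, and 3, 2 and 5 of 340 tests of lists without a planted change were called. Members were drawn independently there, so correlation between members was not part of that simulation. For the overlap, a planted covariance of −0.162 was recovered as −0.152.

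Hairpins were placed with the GENCODE M21 annotation of GRCm38, by the name of the hairpin gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.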

Results

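Small RNA was sequenced from the kidneys of 3 groups of mice with 6 libraries each. The control group was C57BL/6J mice given 0.9% saline. The diabetic nephropathy group (DN) was C57BL/KsJ mice given saline, and the treated group was C57BL/KsJ DN mice given germacrone, a plant sesquiterpene, at 10 mg/kg/day. Total counts were 3700672 to 6654035 in control, 3645173 to 7239343 in DN and 3657879 to 5972069 in treated libraries. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical. Strain differed between control and both DN groups, so strain and disease cannot be told apart in either comparison against control.

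Averaged over all 18 libraries, miR-30a-5p was the most abundant entry at 63200 CPM, followed by miR-21a-5p at 60740, miR-30e-5p at 39870, miR-30c-5p at 37550 and miR-143-3p at 36470 CPM. The order differed between libraries: miR-21a-5p came first in DN 1, DN 2, DN 5, treated 1 and treated 6, miR-143-3p in control 4 and miR-30a-5p in the others. The miR-30 family is abundant in podocytes and tubules, and miR-143-3p is a smooth muscle miRNA. DN 2 stood apart from the other DN libraries: miR-21a-5p made up 22.6% of its counts, against 5.41% to 7.51% for the most abundant entry of each other DN library. Median correlation of log2 CPM with the own group was 0.896 in DN 2, 0.926 in DN 3 and 0.946 in control 2, against 0.958 to 0.973 in the other libraries. The biological coefficient of variation was 0.5. None of the 45 pairs of libraries within a group agreed within counting noise, since the smallest chi-square per degree of freedom was 64.4. That value takes in counting error only, not the spread between samples or library preparations.

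DN against control asked which kidney miRNAs differ in diabetic nephropathy. miR-802-5p, a miRNA raised in the liver of obese mice, was at 184 ± 113 CPM in DN and 35.1 ± 23.3 in control (n = 6 each), with a log2FC of 2.39 (SE 0.507, CI 1.33 to 3.45, 5.25-fold, adjusted p = 0.0806) and 6 of 6 DN libraries above the control median. Its other arm, miR-802-3p, was at 19.1 ± 14.5 against 2.26 ± 2.38 CPM (log2FC 3.10, SE 0.798, adjusted p = 0.277, 5 of 6). miR-204-5p, an epithelial miRNA encoded in an intron of Trpm3, was at 929 ± 234 against 458 ± 92.0 CPM (log2FC 1.02, SE 0.226, 2.03-fold, adjusted p = 0.0806, 6 of 6). miR-21a-5p, which is raised in injured and fibrotic kidney, was at 78010 ± 56800 against 31730 ± 14520 CPM (log2FC 1.30, SE 0.400, adjusted p = 0.277, 5 of 6). Its log2FC was 0.82 without DN 2, where it reached 188700 CPM. None of these miRNAs passed the threshold.

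Among the other miRNAs of smallest p that were higher in DN, miR-196a-2-3p, from the HoxC locus, was at 11.8 ± 2.43 against 6.14 ± 2.17 CPM (log2FC 0.94). miR-147-3p, induced in macrophages by Toll-like receptor signals, had a log2FC of 4.80 (SE 1.39) that rested on DN 2, with 149 CPM there and 0 to 5.46 in the other DN libraries, and was 1.28 without DN 2. Those lower in DN were miR-193a-3p, reported to target Wt1 in podocytes (log2FC −0.88, SE 0.263), miR-99a-3p (log2FC −0.80), the muscle miRNA miR-133a-3p (log2FC −0.97) and miR-219a-1-3p (log2FC −1.30). miR-708-5p was at 29.9 ± 2.93 CPM in DN and 64.8 ± 43.5 in control, with a log2FC of −1.12 that was −0.66 without control 4. For these 5 lower miRNAs the adjusted p was 0.277 and 6 of 6 DN libraries lay below the control median. miR-188-3p (log2FC −0.22, adjusted p = 0.959), miR-192-5p (0.39, 0.825), miR-29c-3p (−0.0033, 0.999), miR-200a-3p (0.14, 0.935) and the red-cell miRNA miR-451a (−0.17, 0.935) had smaller differences. miR-188-3p was near the floor, at 0 CPM in DN 1 and 1.632 to 3.811 CPM in the other DN libraries. Its log2FC ranged from −0.46 to 0.26 over 30 alternatives, so these data do not show it unchanged. For miR-192-5p the log2FC was 0.62 without DN 2 (adjusted p = 0.255), and it passed with limma-voom (0.75, 0.0185) and without control 2, DN 2 and DN 3 (0.67, 0.0335).

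As a group, injury- and fibrosis-associated miRNAs rose in DN against other miRNAs, with 14 of 15 tested entries higher (camera adjusted p = 0.0416). The call was lost at an adjusted p = 0.866 with an estimated correlation. Examples are miR-21a-3p with a log2FC of 1.06, miR-199a-5p with 0.51 and miR-214-3p with 0.39. The rise rested on DN 2, whose mean log2 level on this list was 1.83 against −0.601 to 0.0615 in the other DN libraries: without DN 2, 9 of 15 entries were higher, the test pointed down and the adjusted p was 0.937. The call also ended, at 13 or 14 of 15 higher, without DN 3 (0.0889) and without control 1, 3, 5 or 6 (0.0793, 0.0818, 0.0776 and 0.0685). Leukocyte miRNAs, a marker list with 9 of 9 entries higher and an adjusted p of 0.637, had a level of 3.5 in DN 2 and −0.801 to −0.225 in the other DN libraries. Without DN 2, 0 of 9 leukocyte entries were higher in DN than in control (adjusted p = 0.00227, and adjusted p = 0.296 with an estimated correlation), among them the lymphocyte miRNA miR-150-5p at a log2FC of −1.21 and the macrophage and lymphocyte miRNA miR-146a-5p at −1.26.

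By the edgeR quasi-likelihood test, 0 of 619 entries passed in DN against control, with 47 at an unadjusted p under 0.05 (32 higher and 15 lower, 31 by chance) and 0 with separated groups. DESeq2 called 4, limma-voom with sample weights 91, the edgeR 4 method 6 and the stricter filter 2. Leaving out 1 library gave 6 calls without DN 2, 6 without DN 3 and 1 without control 2, and leaving out all 3 of these gave 51 (31 higher and 20 lower). By name, the fit without these 3 called 28 higher and 17 lower, and limma-voom 39 higher and 38 lower. Adjusted over the list alone, miR-204-5p passed in the kidney-enriched list (0.00286), miR-802-5p (0.00319), miR-802-3p (0.0103) and miR-223-3p (0.021) in the nutrient-sensing list, miR-147-3p, miR-21a-5p and miR-223-3p (0.0177 each) in the NF-kB list, miR-223-3p (0.0435) among leukocyte miRNAs and miR-133a-3p (0.0181) in striated muscle, against 0 over all entries. For miR-223-3p, the log2FC of 3.23 was −0.17 without DN 2. Adjustment over a list alone takes no account of the number of lists.

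**Figure D1:**
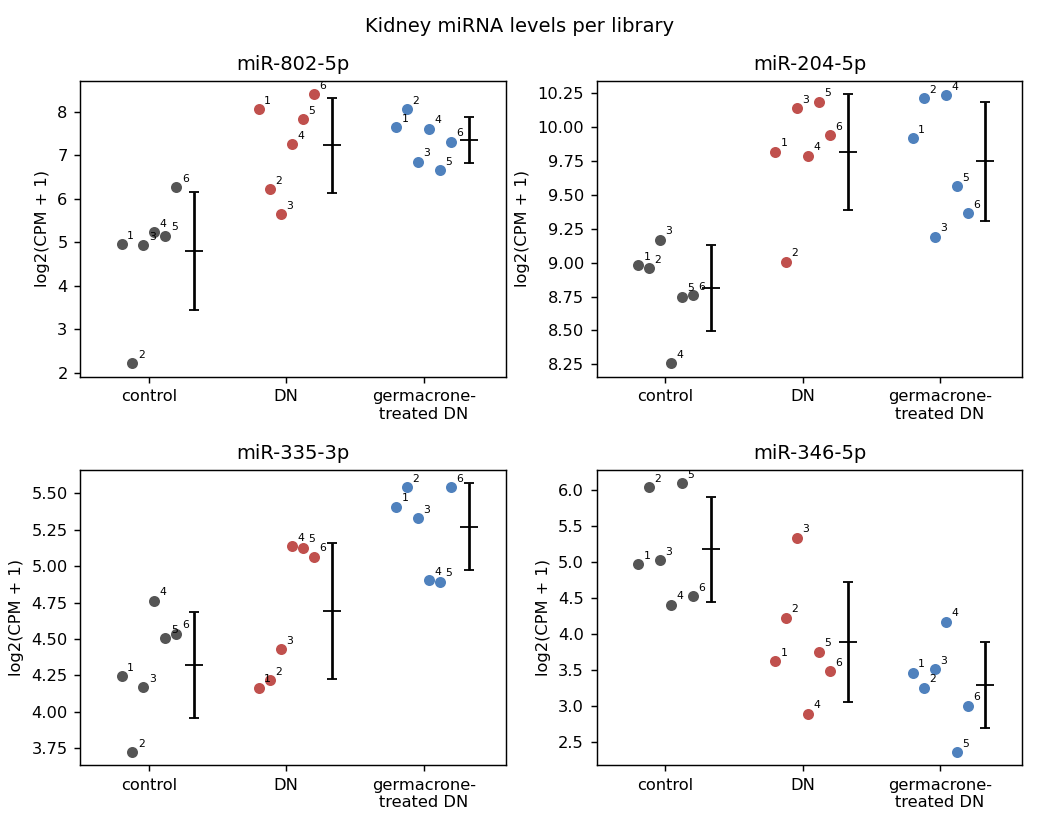
Levels of miR-802-5p, miR-204-5p, miR-335-3p and miR-346-5p as log2(CPM + 1) in each of the 18 libraries, numbered by replicate, with black bars for the group mean ± SD. The means of both DN groups lie above that of control for miR-802-5p, where control 2 is at 3.662 CPM and the other controls at 29.51 to 75.81.

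Treated against DN asked which miRNAs germacrone changes, which the series title links to protection in diabetic nephropathy. miR-335-3p and miR-335-5p, both arms of a hairpin in an intron of the imprinted gene Mest, were higher in treated kidneys: miR-335-3p was at 38.3 ± 7.73 CPM against 25.9 ± 8.40 in DN (log2FC 0.56, SE 0.245) and miR-335-5p had a log2FC of 0.64. miR-1191a (log2FC 0.75), miR-125b-2-3p (0.38) and miR-22-3p (0.35) were also higher. All 5 lay above the DN median in 6 of 6 treated libraries, at an adjusted p of 0.800. Lower in treated kidneys were 3 leukocyte miRNAs whose DN mean rested on DN 2: the myeloid miR-223-3p (106 ± 56.5 against 921 ± 2047 CPM, log2FC −3.13, lower in 3 of 6), miR-150-5p (98.6 ± 24.7 against 308 ± 502, −1.64) and miR-155-5p of activated immune cells (98.7 ± 18.3 against 295 ± 478, −1.58, lower in 1 of 6). Without DN 2, their log2FC was 0.26, −0.11 and −0.11.

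miR-489-3p, encoded in an intron of Calcr, had a log2FC of −0.95 (lower in 5 of 6 libraries), which was −0.50 without DN 2. miR-138-5p had −0.60 (lower in 6 of 6), at 7.87 CPM in treated and 12 in DN. The adjusted p of these 5 lower miRNAs was 0.800. Injury-linked miR-21a-5p was at a log2FC of −0.11 (adjusted p = 0.986), which was 0.37 without DN 2. miR-188-3p (log2FC 0.049, adjusted p = 0.991), miR-192-5p (0.14, 0.959), miR-29c-3p (0.26, 0.880), miR-200a-3p (0.44, 0.800) and miR-451a (0.26, 0.895) did not pass. The low-count miR-188-3p reversed in 17 of 30 alternatives (−0.27 to 0.29), so its direction is not settled here.

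Of the lists, the miR-30 family rose in treated against DN kidneys, with 5 of 5 members higher (camera adjusted p = 0.00458): miR-30a-5p was at 77510 against 57760 CPM, miR-30e-5p at 51690 against 36140 and miR-30c-5p at 46050 against 33690. Its adjusted p was 0.864 with an estimated correlation, and 4 of 5 members were higher under library size only. In DN 2, miR-30a-5p was at 19480 CPM against 50830 to 81470 in the other DN libraries, and without DN 2, 4 of 5 members were higher (adjusted p = 0.0495, and adjusted p = 0.392 with an estimated correlation). The call ended without control 2, DN 2 and DN 3 (adjusted p = 0.103, 5 of 5 higher). The miR-29 and miR-200 families, reported to restrain matrix genes and epithelial-mesenchymal transition, also rose, with 11 of 12 entries higher (adjusted p = 0.00701, and adjusted p = 0.866 with an estimated correlation). Among these, miR-141-3p had a log2FC of 0.58, miR-200a-3p 0.44 and miR-29a-3p 0.19. Under library size only 8 of 12 were higher, and without DN 2 the call ended with 7 of 12 higher (adjusted p = 0.318).

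Imprinted Dlk1-Dio3 miRNAs fell in treated against DN kidneys, with 2 of 30 entries higher (camera adjusted p = 8.5e-06, and adjusted p = 0.866 with an estimated correlation). Examples are miR-127-3p (log2FC −0.41), miR-434-3p (−0.84) and miR-329-3p (−1.33). Rodent-specific miRNAs of the Sfmbt2 intron fell as well, with 0 of 7 higher (adjusted p = 0.0172, and adjusted p = 0.866 with an estimated correlation), among them miR-669c-5p at −0.94 and miR-467c-5p at −2.20. DN 2 held high levels of both, 1.99 for Dlk1-Dio3 and 2.19 for Sfmbt2 miRNAs. Without DN 2, 12 of 30 Dlk1-Dio3 entries were higher (adjusted p = 0.141) and 2 of 7 Sfmbt2 entries (adjusted p = 0.564). The Sfmbt2 call also ended without DN 1 (0.0835), treated 3 (0.053) or treated 6 (0.0771). All 9 leukocyte entries were lower in treated kidneys (adjusted p = 0.0528), against 6 of 9 higher without DN 2 (0.0874). With any 1 of the other DN libraries or treated 6 left out this test passed, at 0.0141 to 0.0358, and gave an adjusted p = 0.778 to 0.942 with an estimated correlation. The miR-183, miR-96 and miR-182 cluster had 3 of 3 higher (adjusted p = 0.113), which passed without DN 2 (0.00146). The level of DN 2 on this cluster, 1.02, lay above every treated library. Without DN 2, injury- and fibrosis-associated miRNAs also passed with 11 of 15 higher (0.0495) in place of 2 of 15 (0.457). So did the let-7 family with 0 of 8 higher (0.0107), miR-17-92 and its paralogs with 11 of 12 (0.0108) and smooth muscle miRNAs with 6 of 8 (0.0495). On the let-7 list DN 3 lay at a level of 0.66, against −0.269 to 0.0241 in the other DN libraries. With an estimated correlation, 0 of 57 list tests passed without DN 2 or any other library.

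By edgeR, 0 of 619 entries passed in treated against DN, with 23 at an unadjusted p under 0.05 (5 higher and 18 lower, 31 by chance), and DESeq2, limma-voom and every other alternative run also gave 0. The liver list had 1 tested entry, miR-122-5p, the abundant miRNA of liver (log2FC −1.50, 17.3 ± 15.5 against 49.0 ± 47.1 CPM). Adjusting over that list alone changes nothing, so its value of 0.0429 is the unadjusted p of the edgeR test. It is among the 23 entries above, which are fewer than chance gives, and 0 passed over all entries.

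**Figure D2:**
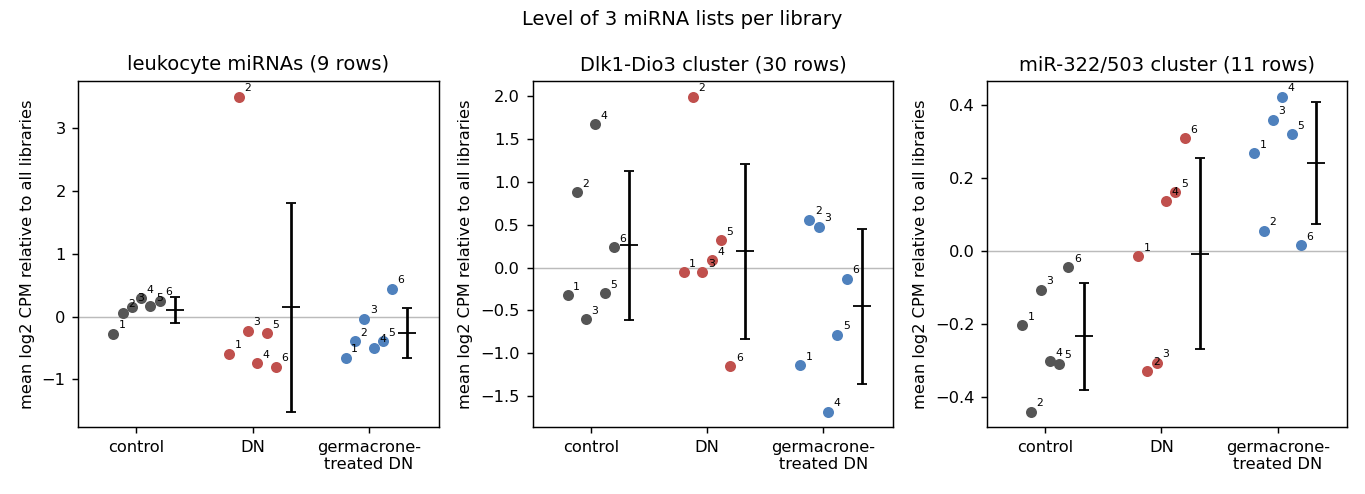
Mean log2 CPM relative to all libraries for leukocyte miRNAs (9 entries), the Dlk1-Dio3 cluster (30) and the miR-322 and miR-503 cluster (11) in each library, numbered by replicate. DN 2 lies at 3.5 for leukocyte miRNAs, above the other DN libraries at −0.801 to −0.225.

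Treated against control asked how far kidneys of germacrone-treated DN mice differ from those of control mice. miR-802-5p was at 172 ± 61.4 CPM against 35.1 ± 23.3 in control (log2FC 2.30, SE 0.507, CI 1.24 to 3.36, 4.91-fold) and miR-204-5p at 893 ± 267 against 458 ± 92.0 (log2FC 0.96, SE 0.226), both with separated groups and an adjusted p of 0.0945. miR-346-5p, encoded in an intron of the glutamate receptor gene Grid1, was at 9.51 ± 4.32 against 39.4 ± 21.3 CPM (log2FC −2.05, SE 0.436, adjusted p = 0.0945, separated). miR-335-3p of the Mest intron was at 38.3 ± 7.73 against 19.5 ± 4.86 CPM (log2FC 0.97, SE 0.246, adjusted p = 0.141, separated). let-7b-5p, a member of a family that restrains growth genes, was at 13020 ± 1901 against 22560 ± 5635 CPM (log2FC −0.79, adjusted p = 0.148, separated).

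miR-802-3p had a log2FC of 3.14 and miR-450b-5p of 1.06, both with separated groups and an adjusted p of 0.148. Lower by smallest p were miR-133a-3p (log2FC −1.05, adjusted p = 0.148), miR-99a-3p (−0.82, 0.170) and the neuronal miR-124-3p (−4.89, 0.148), whose log2FC was −2.51 without control 4 at 324.9 CPM. miR-21a-5p was higher than the control median in 6 of 6 treated libraries (log2FC 1.19, adjusted p = 0.173). miR-188-3p (log2FC −0.17, adjusted p = 0.905), miR-192-5p (0.53, 0.432), miR-29c-3p (0.26, 0.674), miR-200a-3p (0.58, 0.251) and miR-451a (0.091, 0.901) did not pass. The log2FC of the low-count miR-188-3p ranged from −0.44 to 0.18 over 30 alternatives.

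Relative to other miRNAs, Dlk1-Dio3 miRNAs fell in treated against control kidneys, with 2 of 30 entries higher (camera adjusted p = 0.00235, and adjusted p = 0.866 with an estimated correlation). Examples are miR-434-3p (log2FC −0.91) and miR-381-3p (−0.87). The cluster's level was highest among controls in control 4, at 1.67, and without control 4 the call ended with 8 of 30 higher (adjusted p = 0.0996). Members of the X-linked miR-322 and miR-503 cluster rose, with 9 of 11 higher (adjusted p = 0.0263, and adjusted p = 0.864 with an estimated correlation), among them miR-542-3p (log2FC 1.23), miR-450b-5p (1.06) and miR-322-5p (0.66). fry also called this list (adjusted p = 0.0305), and the camera call ended without control 1 (0.0603) or control 4 (0.0782).

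By edgeR, 0 of 619 entries passed in treated against control, with 121 at an unadjusted p under 0.05 (66 higher and 55 lower, 31 by chance) and 32 with separated groups (5.17%, against 0.216% by chance). DESeq2 called 18, limma-voom 106, the fit of only these 2 groups 56 and the edgeR 4 method 3. Some names stand on more than 1 entry, and the 32 separated entries carried 28 names. By name, DESeq2 called 7 higher and 7 lower, limma-voom 56 and 36, and the fit of only these 2 groups 24 and 22. DN libraries are not compared here but are part of the shared fit: 7 entries were called without DN 2, 3 without DN 3, and 50 (29 higher and 21 lower, by name 28 and 15) without control 2, DN 2 and DN 3. Adjusted over the list alone, miR-204-5p (0.00504), miR-10a-5p and miR-10b-5p (0.0448 each) passed in the kidney-enriched list, let-7b-5p (0.0209) in the let-7 family, and miR-802-5p (0.00469) and miR-802-3p (0.00927) in the nutrient-sensing list, against 0 over all entries. So did miR-133a-3p (0.0104), miR-124-3p and miR-375-3p (0.0313 each), miR-7a-5p (0.0474), miR-542-3p (0.0303) and miR-450b-5p (0.0193) in their lists. These values are not adjusted for the number of lists.

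No miRNA passed in both DN against control and treated against DN, so 0 were called in opposite directions. At an unadjusted p under 0.05, 6 were opposite: miR-130b-3p, miR-138-5p, miR-147-3p, miR-223-3p and miR-489-3p were higher in DN and lower with germacrone, and miR-22-3p was lower in DN and higher with germacrone. The DN libraries are shared by both comparisons, and simulations without a difference between any groups gave a mean of 6.36 such miRNAs (highest 13). Independent lists would give 0.931 and 0.121 in those directions. A DN difference without a germacrone effect was not simulated, so the simulations do not test an effect of germacrone alone. Across miRNAs, which are not independent replicates, the log2FC of both comparisons correlated at −0.209, against −0.497 (−0.67 to −0.346) in the simulations, and the covariance exceeded the simulated mean by 0.0543. With DN libraries split into sets of 3, the mean correlation over 20 splits was 0.306 (−0.0121 to 0.582, 1 below 0), and 0 miRNAs were opposite at an unadjusted p under 0.05.

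The other lists did not pass the threshold with all libraries and TMM factors, and their camera adjusted p follows in the order DN against control, treated against DN and treated against control. Kidney-enriched miRNAs gave 0.457, 0.311 and 0.187, with 8, 7 and 7 of 11 entries higher. The let-7 and miR-98 family gave 0.531, 0.0962 and 0.111, with 4, 0 and 1 of 8 higher. Under library size only the let-7 family passed in treated against DN (0.0303) and in treated against control (0.0311), with 0 of 8 higher in both and 0 of 57 tests passing with an estimated correlation. miR-17-92 and its paralogous clusters gave 0.457, 0.311 and 0.206, with 9, 7 and 10 of 12 higher. The list for hypoxia, oxidative stress and nutrient sensing gave 0.315, 0.929 and 0.457, and that for NF-kB and innate inflammation 0.645, 0.536 and 1. Endothelial miRNAs gave 0.775, 0.457 and 0.913, and smooth muscle, mesangial and pericyte miRNAs 0.929, 0.637 and 0.853. Red-cell miRNAs gave 0.939, 0.929 and 0.929, striated muscle miRNAs 0.299, 0.539 and 0.745, and nerve, adrenal and islet miRNAs 0.995, 0.539 and 0.719. miR-188 and its Clcn5 neighbours gave 0.919, 0.674 and 0.929.

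For lists called in 1 comparison, injury- and fibrosis-associated miRNAs gave an adjusted p of 0.457 in treated against control, and the miR-29 and miR-200 families 0.457 both in DN against control and in treated against control. The miR-30 family gave 0.815 in DN against control and 0.186 in treated against control, and Sfmbt2 miRNAs 0.929 and 0.113. The Dlk1-Dio3 cluster gave 0.653 in DN against control, where it passed without DN 2 with 3 of 30 higher (0.0108, and adjusted p = 0.695 with an estimated correlation), and the miR-322 and miR-503 cluster gave 0.208 there and 0.0727 in treated against DN. Leukocyte miRNAs gave 0.457 in treated against control, and the miR-183, miR-96 and miR-182 cluster 0.916 in DN against control and 0.457 in treated against control. Liver miR-122-5p had no test as a list and had a log2FC of 1.26 (SE 0.675, adjusted p = 0.684) in DN against control and of −0.24 in treated against control.

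Median and test differed in sign in 8 of 57 list tests. In DN against control these were Sfmbt2 miRNAs (median log2FC 0.53, test down), the miR-30 family (0.033, test down; −0.075 under library size only), endothelial miRNAs (0.021, test down), the miR-183, miR-96 and miR-182 cluster (0.038, test down) and miR-188 with its neighbours (−0.0014, test up). The others were nutrient sensing in treated against DN (−0.097, test up) and in treated against control (−0.069, test up), and the NF-kB list in treated against control (−0.093, test up). Median and mean differed in sign in 10 tests. In DN against control these were smooth muscle (−0.038 and 0.094), endothelial (0.021 and −0.019), Dlk1-Dio3 (−0.062 and 0.012) and miR-188 (−0.0014 and 0.027) lists. In treated against DN they were the smooth muscle (0.0065 and −0.054), red-cell (0.00035 and −0.12) and nerve lists (0.24 and −0.0025), and in treated against control the NF-kB (−0.093 and 0.18), nutrient-sensing (−0.069 and 0.40) and nerve lists (0.14 and −0.40). Mean and test also differed in 10 tests, among them nutrient sensing in treated against DN (mean −0.40, test up) and the Sfmbt2 list in DN against control (mean 0.40, test down). Library size only shifted the median log2FC of all entries by −0.075, −0.14 and −0.2 in the 3 comparisons, so medians near 0 can change sign with the scaling. List tests are relative to the other miRNAs. In DN against control the Sfmbt2 median of 0.53 lay above the median of 0.075 over all entries, yet the test pointed down. The cause of that difference was not tested.

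Hairpin positions are given on GRCm38. Mir802 lies on chromosome 16 from 93369720 to 93369816, between genes, and Mir204 on chromosome 19 from 22750605 to 22750672, in an intron of Trpm3. Mir335 lies on chromosome 6 from 30741299 to 30741396, in an intron of Mest, and Mir346 on chromosome 14 from 34894609 to 34894706, in an intron of Grid1. Mir21a lies on chromosome 11 from 86584067 to 86584158, in an exon of Vmp1, and Mirlet7b on chromosome 15 from 85707319 to 85707403, in an exon of Lncppara. Mir450b lies on the X chromosome from 53047997 to 53048078, between genes, and Mir188 on the X chromosome from 7247989 to 7248056, in an intron of Clcn5. miR-124-3p, miR-133a-3p, miR-138-5p and miR-30c-5p are each encoded by more than 1 hairpin, whose reads the counts do not tell apart.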

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

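Tests of white blood cells, whole blood, the diabetic state, a wrong label of DN 3, liver RNA, the outlying libraries, the strain and the splits with libraries left out anew were chosen only after the result was seen, whereas GC content, a label swap and the other splits were set out before it.

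Of 135 groups of 6 values tested for a single distant value, 17 had one, and 8 of these were in DN 2. The values tested were named miRNAs, library measures, the called lists and the leukocyte list. Many were picked by their values in these data and several move together, so the usual chance rate of about 1 in 20 does not apply to them. Leukocyte miRNAs stood far above the other DN libraries in DN 2, at a level of 3.5 against −0.801 to −0.225, with miR-223-3p at 5099 CPM (others 43.46 to 139) and miR-150-5p at 1330 (73.93 to 132.4). White blood cells in this kidney sample stay open as a candidate explanation: 9 of 9 leukocyte entries were at least 2-fold above the median of the other DN libraries, by 8.34- to 63-fold, which restates the pattern and decides nothing, and 3 of the 9 are also on another list and 7 were above 10 CPM in every library other than DN 2. Whole blood left in the sample is argued against by the red-cell miRNAs, whose median log2 ratio was −2.26. As a trait shared by the DN group, the diabetic state is argued against by the other DN libraries, 0 of 5 of which lay above every control. An effect of disease on single samples was not tested.

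Control 2 and DN 3 shared a profile, with deviations from their groups correlated at 0.718 across miRNAs, against 0.503 for the next pair. GC content of the hairpins may have a part in it, since the deviations correlated with GC at rank correlations of 0.352 and 0.343, against −0.334 to 0.275 in the other libraries (403 of 426 names had a matched hairpin). An exchange of these labels is argued against, because control 2 lay nearer the DN group in 4% of 50 entries, while DN 3 lay nearer control in 84%. DN 3 as a control library under a wrong label cannot be told apart from a DN library with an unusual profile: DN 3 lay nearer control in 75% of 28 miRNAs, but so did DN 2, against 3.57% to 39.3% for the other DN libraries, and miR-204-5p was at 1127 CPM in DN 3, above every control. No biological explanation was tested for this pair.

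miR-802-5p, miR-802-3p and miR-204-5p were higher in both DN groups than in control. Liver RNA, as a source of miR-802, is argued against by liver miR-122-5p, which lay below miR-802-5p in 11 of 12 libraries of the DN groups, although miR-122-5p itself had a log2FC of 1.26 in DN against control (adjusted p = 0.684). The outlying libraries are argued against as the cause, since without control 2, DN 2 and DN 3 the log2FC kept at least 107% of its size in DN against control and at least 88.5% in treated against control. Disease and strain cannot be told apart, because 0 control libraries were of strain C57BL/KsJ, so a difference of C57BL/6J from C57BL/KsJ mice may give these values.

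Other distant values in DN 2 were miR-204-5p at 513.4 CPM (others 884.2 to 1166), miR-30a-5p at 19480 (50830 to 81470) and miR-30c-5p at 10840 (29960 to 44230), the most abundant entry at 22.6% of counts (5.41 to 7.51), and the injury and fibrosis list at a level of 1.83 (−0.601 to 0.0615). In control 2, miR-802-5p was at 3.662 CPM (others 29.51 to 75.81) and miR-451a at 1210 (2528 to 3400). In control 5, miR-99a-3p was at 10.24 CPM (17.16 to 23.06) and miR-125b-2-3p at 115.6 (162 to 177). let-7b-5p was at 31560 CPM in DN 3 (10350 to 14700). In DN 1, miR-708-5p was at 35.48 CPM (27.45 to 30.2) and miR-188-3p at 0 (1.632 to 3.811). miR-138-5p was at 5.014 CPM in control 1 (7.931 to 8.952) and at 5.65 in treated 3 (7.7 to 8.813).

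Other splits of the libraries asked how often chance gives as large a result, with 100 drawn for each result and the real grouping counted among the splits. In DN against control chance could not be excluded, for 47 entries at an unadjusted p under 0.05 (36 splits gave as many, highest other 178) or for 1 list call (96 splits, highest 9). The split with 178 set controls 1 to 5 and DN 3 against the rest, which points to a structure of the samples. In treated against DN chance could not be excluded for 23 entries (88 splits, highest 128) or 4 list calls (59 splits, highest 8). In treated against control 2 splits, the real one included, gave as many as 121 entries (highest other 127), under the 5% set beforehand. That makes chance unlikely for this count without excluding it, as several such tests were run. For 2 list calls chance could not be excluded (32 splits, highest 3). Without control 2, DN 2 and DN 3, only the real split gave as many as 50 calls in treated against control (highest other 36). This makes chance unlikely for this count without excluding it. Several such tests were run, and these 3 libraries were left out after the data were seen. They correlated least with their group in 100 of 100 splits, so leaving them out did not favour the real grouping. DN 2 and DN 3 kept their group in every split of this comparison, so their low correlation was fixed beforehand. Picking the 3 anew left out the same libraries here, so it repeated the test on other splits (1 split, highest other 46) and is no separate check. The split with 46 calls had 178 entries at an unadjusted p under 0.05, against 168 in the real one. In DN against control the same 3 were picked in only 64 splits, so the count with these 3 left out (51 calls, 1 split, highest other 41) decides nothing. Picked anew, 4 splits gave as many as 51, the real one among them, which is under 5%. Other groupings among these gave 95, 239 and 241 calls, more than the real one, so this count decides nothing about chance either.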

How the results depend on the processing

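Leaving out control 2, DN 2 and DN 3 together, the robust prior, the edgeR 4 method, the authors' factors, equal entries kept once and list tests with a library left out or with an estimated correlation on such alternatives were chosen only after the result was seen, as was the choice to follow called lists and leukocyte miRNAs one by one. Treated against DN had 0 calls under every alternative run. DN against control had 0 calls in edgeR but 2 with the strict filter, 4 with DESeq2, 91 with limma-voom, 6 with the edgeR 4 method, 51 without the 3 libraries and 0 to 6 with 1 library left out. Treated against control had 18 with DESeq2, 106 with limma-voom, 56 with only these 2 groups, 3 with the edgeR 4 method, 50 without the 3 libraries and 0 to 7 with 1 library left out. limma-voom gave DN 2 a weight of 0.0851, DN 3 0.199 and control 2 0.241, against 0.832 to 2.89 in the others; the cause was not tested. Of 57 list tests 7 passed, 0 with an estimated correlation (with all libraries, with any 1 left out, without the 3 and under library size only), 1 with fry, 9 under library size only, 6 with the replicate block (which ended the injury and fibrosis call, 0.0799), 13 without the 3 libraries and 5 to 12 with 1 library left out. The opposite overlap of 0 was 6 at an unadjusted p under 0.05. Of the named miRNAs' values under alternatives, 1325 kept direction and side of the threshold, 86 passed it and 65 reversed. Of the followed lists' values, 185 kept both, 32 no longer passed, 6 newly passed and 7 reversed. miR-802-5p ranged from a log2FC of 2.19 to 2.77 in DN against control (adjusted p 0.000359 to 0.36) and miR-204-5p from 0.93 to 1.17 (0.00376 to 0.341). In treated against control miR-346-5p ranged from −2.29 to −1.82 (0.00128 to 0.224).

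Reversed log2FC values under limma-voom were, in DN against control, miR-188-3p 0.26 and miR-29c-3p 0.20, in treated against DN miR-223-3p 0.34, miR-150-5p 0.0053, miR-155-5p 0.30, miR-188-3p −0.27, miR-21a-5p 0.14, miR-192-5p −0.19 and miR-451a −0.014, and in treated against control miR-451a −0.17. Without the 3 libraries they were miR-29c-3p 0.22 in DN against control, miR-223-3p 0.54, miR-150-5p 0.029, miR-155-5p 0.41, miR-188-3p −0.011, miR-21a-5p 0.17, miR-192-5p −0.28 and miR-29c-3p −0.087 in treated against DN, and miR-451a −0.075 in treated against control. In DN against control miR-29c-3p was 0.019 without a filter, 0.050 with only the 2 groups and 0.0033 with names summed. In treated against DN miR-188-3p was −0.057 with library size only, −0.0017 with the replicate block, −0.025 with only the 2 groups, −0.0087 with the edgeR 4 method and −0.0069 with the authors' factors. In treated against control miR-451a was −0.10 with library size only. With 1 library left out, values that reversed spanned −0.46 to 0.13 for miR-188-3p and −0.067 to 0.17 for miR-29c-3p in DN against control. In treated against DN they spanned −3.45 to 0.26 for miR-223-3p, −0.25 to 0.29 for miR-188-3p, −0.36 to 0.37 for miR-21a-5p and −0.092 to 0.28 for miR-192-5p, and in treated against control −0.44 to 0.18 for miR-188-3p and −0.046 to 0.31 for miR-451a. Injury and fibrosis miRNAs in DN against control reversed without the 3 libraries (adjusted p 0.811), with 0.00231 to 0.937 over single libraries left out. Leukocyte miRNAs reversed in DN against control with the replicate block (0.947) and without the 3 libraries (0.00309), with 0.00227 to 0.805 over single libraries, and in treated against DN without the 3 libraries (0.00804), with 0.0141 to 0.159. With 1 library left out, both lists reversed only without DN 2, which the fit without the 3 libraries also lacks. The cause of the other reversals was not tested. Replicate numbers did not pair the samples: libraries of the same number correlated at a median of −0.0053 over 18 pairs, others at 0.044. At this depth 565 entries stayed under the count filter and could not be tested there.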

Other observations

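Values below were picked, and the fits without DN 2 or the 3 outlying libraries chosen, only after the result was seen.

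miR-150-5p, a miRNA of mature B and T lymphocytes, was at 155 to 324 CPM in the 6 control libraries. It was at 71.2 to 124 CPM in the 6 treated libraries and at 73.9 to 132 in the 5 DN libraries other than DN 2, all below every control. Its log2FC without DN 2 was −1.21 in DN against control and −1.32 in treated against control. In DN 2 itself miR-150-5p was at 1330 CPM. With that library kept, 9 of 9 leukocyte entries, miR-150-5p among them, were higher in DN than in control. The leukocyte list as a whole was lower in DN than in control without DN 2 (0 of 9 higher, adjusted p = 0.00227, and adjusted p = 0.296 with an estimated correlation), and in treated against control 4 of 9 were higher (adjusted p = 0.141). With all libraries that count was 4 of 9 with TMM factors and 0 of 9 under library size only, and the difference between these comparisons was not tested.

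Kidney-enriched miRNAs, markers of renal epithelium, were higher in DN than in control in 10 of 11 entries without DN 2 (adjusted p = 0.0107, and adjusted p = 0.366 with an estimated correlation) and in 10 of 11 without control 2, DN 2 and DN 3 (adjusted p = 0.0242, and adjusted p = 0.368 with an estimated correlation). Among them, without DN 2, miR-204-5p had a log2FC of 1.17, miR-192-5p 0.62 and miR-10b-5p 0.45. The miR-183, miR-96 and miR-182 cluster, known from sensory cells, was higher in treated than in DN kidneys without DN 2 in 3 of 3 entries (adjusted p = 0.00146, and adjusted p = 0.296 with an estimated correlation), with miR-96-5p at a log2FC of 0.80, miR-182-5p at 0.78 and miR-183-5p at 0.49. DN 2, left out there, was at a level of 1.02 on this cluster, above every treated library. Treated 3 (0.974) and treated 5 (0.868) lay above the other treated libraries (−0.335 to 0.271). Control 4 lay above the other controls on several lists, among them Dlk1-Dio3 miRNAs at 1.67, striated muscle at 1.33 and nerve, adrenal and islet miRNAs at 1.09.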
